A study of Macaca fascicularis with 3 samples.

How the data were processed

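Single-cell RNA libraries were made from the front of the eye of the cynomolgus macaque (Macaca fascicularis) with 10x Chromium 3' chemistry, in which each captured RNA molecule carries a unique molecular identifier (UMI). Per the labels, eyes were removed right after death, kept on ice for an hour, dissected, digested with papain and dispersed into single cells. The labels give 3 libraries, each the only one of its group: trabecular meshwork at 5 years (chemistry version 2), corneoscleral segment at 5 years (version 2) and corneoscleral segment at 22 years (version 3). The titles of the 3 libraries carry different numbers, and those of the 5-year trabecular and corneoscleral libraries end in R and L. The labels do not say what these mean, or whether the 5-year libraries came from the same animal. Age, chemistry and animal change together between the corneoscleral libraries.

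The deposited table holds raw counts of UMIs per gene and cell, with no normalization by the authors. The submitters' processing notes name Cell Ranger 2.1.0; the genome build and annotation behind the counts were not given in the sources used here. The table has 36162 features and 9155 cells, of which 9366 features are at 0 in every cell and 3138 are unnamed transcripts. The labels give a targeted recovery of 6000 cells per library, and the table holds 1870, 2528 and 4757. All cells were kept as deposited. Each cell had at least 601 detected genes, a floor already present in the table. Of the 15297 features named by an NCBI gene number, 7674 were found in a table of RefSeq genes of the same species and 702 of these received another symbol. A further 1034 genes were listed as a pair of features, marked by suffixes, and the fuller member of a pair stood for a list gene. No mitochondrial gene was among the features, so mitochondrial shares were not computed. No reference genome was used here, so values carry no positions.

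All choices in this paragraph that fix gene lists, marker lists, tests and named genes were made before the data were examined. A set of 5 lists was fixed for testing: glaucoma and eye pressure genes (53 genes), targets of pressure-lowering drugs (27), outflow matrix (35), TGF-beta, BMP, WNT and stretch signalling (31) and vessel growth and tone signalling (24). Another 5 lists were fixed for comparing libraries: immediate early genes (17), heat shock genes (12), senescence genes (15), interferon and antigen presentation genes (16) and oxidative stress genes (18). Cell type markers were fixed as 22 lists. Genes were named by rule. In each class and list, these were up to 4 called genes with the largest absolute log2 fold change and the same direction in every library, and MYOC always. Between libraries, they were the 10 genes with the highest and the 10 with the lowest ratio in the class with the most cells in its smaller library, leaving out ribosomal and unnamed features, and up to 4 members of each list. The text names a subset of these genes; CDKN2B and the genes named in classes other than the leading one between libraries were chosen after their values were seen.

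Cells were clustered with Python 3.11.15, scanpy 1.11.5 and anndata 0.12.19. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across libraries, and 30 principal components were computed without integration. The genes of the 5 tested lists were kept out of the variable genes. A shared-neighbour graph over 15 neighbours was split by leidenalg 0.10.2 at resolution 1. The other 5 lists were not kept out, and some of their members were among the 10 leading genes of a cluster: IGFBP3 of epithelial clusters 3 and 7, MYC of 3, NQO1 of 6, IGFBP5 of fibroblast cluster 24, CCL2 of macrophage cluster 29 and IL6 of unnamed cluster 19. A cluster took the name of the marker list with the highest mean log2 level over the median cluster, with 50 counts per 1000000 UMIs (CPM) added. It needed at least 3 markers at 2-fold or more with at least 10 UMIs. A cluster stayed unnamed when a second list reached 80% of its score with 3 markers, when its 10 leading genes held more markers of another class than of its own, or when its cells were shallow with no own marker leading. Clusters of at least 50 cells torn between names were clustered again at resolution 0.5 with 1000 variable genes. These scoring thresholds were set after the data were seen. Named classes are called like the type whose markers they carried. Scrublet marked 0.909%, 0.633% and 0.126% of cells as doublets in the trabecular, 5-year and 22-year corneoscleral libraries; these cells were kept. So few calls among the 4757 cells of the 22-year library mean that its calls cannot be relied on.

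Differences between cell classes were tested with edgeR 4.0.16 in R 4.3.3. Raw counts were summed per library and class, for classes with at least 20 cells in at least 2 libraries. This gave 25 sums over 9 classes. Each class was compared with the unweighted mean of the log levels of the other classes by edgeR's quasi-likelihood F test with TMM normalization and library as a block, with 14 residual degrees of freedom. Of the 169 genes of the 5 lists, 139 were among the 10118 genes that passed edgeR's expression filter. P-values were adjusted by Benjamini-Hochberg over all genes tested in a class, with a false discovery rate of 0.05, and again over the list alone. The blocks are 3 libraries that differ in dissection, age, animal or chemistry. For each gene, the p-values set a class difference against scatter between libraries that is pooled over the 25 sums. They do not measure how steady 1 class was by itself, and epithelium-like and T or NK cell-like cells had sums from only 2 libraries. The classes were clustered from other genes of the same cells, which these p-values do not take into account. Sums of different classes from 1 library share its cells' preparation. A set of 3 further contrasts fixed in advance could not be run, because Schlemm canal or lymphatic endothelium, trabecular beam cells and pericytes were not named in at least 2 libraries. Only genes of the 5 lists are reported from this test. In 1 simulation of sums for juxtacanalicular cell-like cells, the test recovered 28% of 100 genes with a 2-fold change and 96% of 100 genes with a 4-fold change. It made 4 false calls in all among 7421 genes. The simulation used a dispersion of 0.15 and the same mean profile for every class, and the real fit had a common dispersion of 0.0685.

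Between libraries there was 1 library per group, so no test was run, and these comparisons carry no p-value. For classes with at least 50 cells in both libraries, the ratio of CPM of the summed counts is given with an exact conditional binomial 95% interval. A gene needed at least 50 UMIs over both libraries. A ratio against 0 UMIs was computed with a floor of 3 UMIs. A list's median log2 ratio is given with the 95% range over 2000 Poisson redraws of its counts. It is also placed as a percentile among 10000 random lists matched in 20 bins of mean expression; this placing describes and does not test. Shares of cells have exact Clopper-Pearson 95% intervals, and a share of 0 is given the limit of 3 cells of the total instead. All of these cover counting error only. On fibroblast-like sums simulated by Poisson draws the intervals held the true ratio for 95.9%, 96.3% and 96.0% of genes at ratios of 1, 2 and 4. Such draws follow the model behind the intervals, so this was near certain beforehand. Scatter between cells, clusters or libraries was not simulated.

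Alternatives covered clustering resolution (0.5 and 2), the number of variable genes (1000 and 4000), integration by reciprocal PCA in Seurat 5.3.0, each library clustered alone, cells with at least 1000 UMIs, doublet calls left out, DESeq2 1.42.0 size factors and its Wald test, no expression filter, no block, at least 50 cells per class, cells thinned to 1000 UMIs and each library left out in turn. Between libraries they covered TMM scaling, CPM without ribosomal genes, means over cells and a minimum of 200 UMIs. Alternatives that kept the fibroblast-like clusters apart or restricted the fibroblast-like or epithelial cells to some clusters were added after the data were seen. Tests of technical explanations were revised during the work, and the closing section gives the earlier versions beside the later ones. Some single genes are not reported here, though the counts and medians of their lists include them.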

Results

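The series title places these libraries in an atlas of the tissues that drain aqueous humor from the eye, made to find the cells that express genes of glaucoma. The trabecular meshwork is the filter of the drainage angle, and the corneoscleral segment is the wider ring of tissue that holds it. The trabecular meshwork library at 5 years had 1870 cells and 2828959 UMIs, with a median of 1411 UMIs and 782 genes per cell. The corneoscleral library at 5 years had 2528 cells and 4815266 UMIs, with medians of 1742 UMIs and 932 genes. The corneoscleral library at 22 years had 4757 cells and 40067708 UMIs, with medians of 7353 UMIs and 2407 genes. There were no replicate libraries in any group.

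Connective tissue fibroblast-like cells were the largest class at 5 years, and epithelial cells made up most of the 22-year library. Fibroblast-like cells were 37.8% of the trabecular meshwork library (95% interval 35.6 to 40.0) and 37.2% of the 5-year corneoscleral library (35.3 to 39.1), against 2.86% at 22 years (2.40 to 3.37). Corneal or conjunctival epithelium-like cells, which carry keratins of the ocular surface, were 81.9% of the 22-year library (80.8 to 83.0) and 6.65% of the 5-year corneoscleral library (5.71 to 7.69). None of the 1870 trabecular meshwork cells was epithelium-like, which allows a share of up to 0.160% (3 cells). Juxtacanalicular cell-like cells, named after the layer of the meshwork next to Schlemm's canal, were 3.37% of the trabecular library (2.60 to 4.29), 7.0% of the 5-year corneoscleral library (6.04 to 8.07) and 0.589% at 22 years (0.391 to 0.850).

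Macrophage-like cells made up 20.6%, 16.9% and 0.946% of the trabecular, 5-year and 22-year corneoscleral libraries. Smooth or ciliary muscle-like cells made up 19.9%, 11.9% and 2.82% in the same order, non-myelinating Schwann cell-like cells 8.29%, 5.78% and 0.547%, and pigment cell-like cells 5.99%, 4.71% and 1.85%. Blood vessel endothelium-like cells were 3.05%, 3.44% and 1.37%. T or NK cell-like cells were 0.214%, 0.989% and 2.31%; in the 22-year library their median of 1271.5 UMIs lay far below the library median of 7353. Keratocyte-like cells, the fibroblasts of the corneal stroma, numbered 0, 52 and 3, and corneal endothelium-like cells 6, 18 and 0. No cluster was named from the markers of trabecular beam cells, pericytes, Schlemm canal or lymphatic endothelium, ciliary epithelium, myelinating Schwann cells, B or plasma cells, mast cells, lens or photoreceptors, and the lists for red blood cells and cycling cells name no type. BMP5, a marker of trabecular beam cells, was among the leading genes of fibroblast cluster 4, which held 462 cells of the trabecular library. Beam cells within the fibroblast-like class are thus not ruled out. These shares were counted among the cells kept in the deposited table, and the dissection, the recovery of each cell type and the depth of the chemistry can each set them. The juxtacanalicular naming was the least steady. With 1000 variable genes its share was 0 in the trabecular library and 0.0791% in the 5-year corneoscleral one, and with each library clustered alone no trabecular cell received the name.

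**Figure D1:**
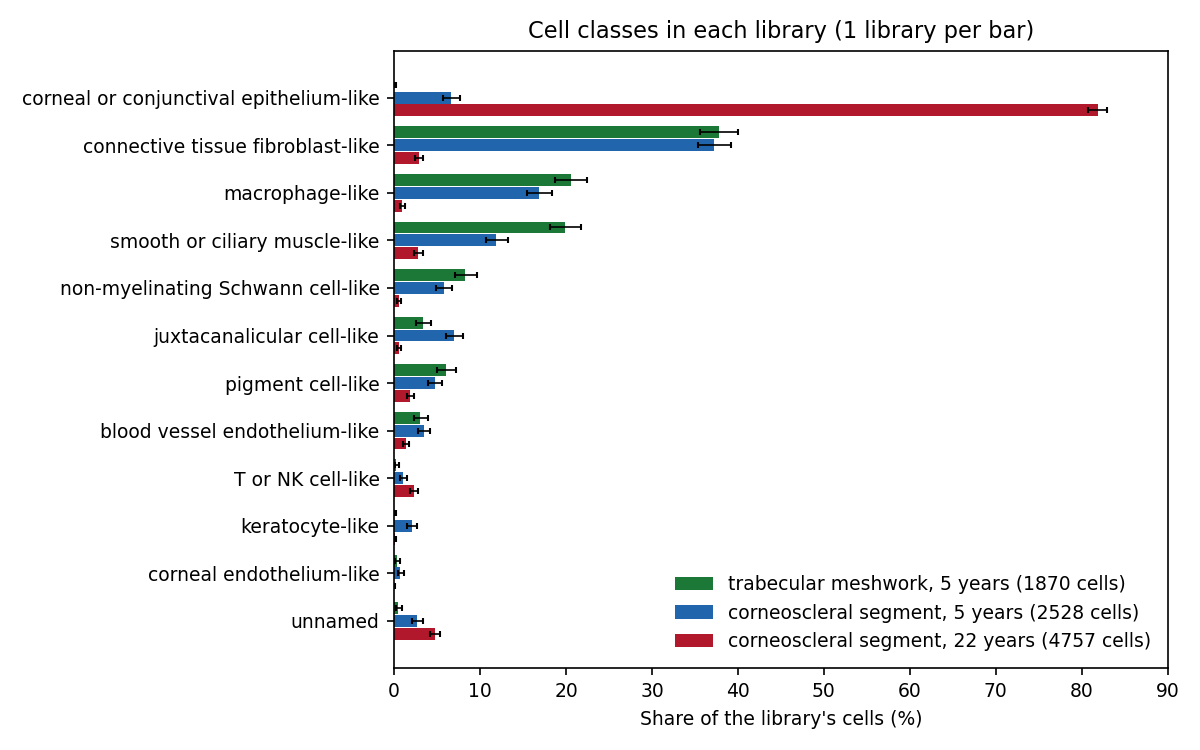
Share of each library's cells (%, horizontal axis) in each named class, 1 bar per library, with exact 95% binomial intervals as error bars. Epithelium-like cells make up 81.9% of the 22-year corneoscleral library and 6.65% of the 5-year one.

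The next comparison asked which cells of the outflow tissue express the genes of the 5 lists. MYOC, the gene for myocilin, whose mutations cause juvenile and adult open-angle glaucoma, was highest in juxtacanalicular cell-like cells. Its level there was 11773 ± 8774 CPM (SD, n = 3 libraries), with a log2 fold change over the mean of the other classes of 6.88 (SE 0.47; adjusted p 3.58e-08 by edgeR's quasi-likelihood test; higher in 3 of 3 libraries). The levels in the trabecular, 5-year and 22-year corneoscleral libraries were 7645, 5823 and 21850 CPM. Almost all juxtacanalicular cell-like cells of the 22-year library lay in a sub-cluster of their own, 27 of 28. LMX1B, a transcription factor mutated in nail-patella syndrome with glaucoma, was also raised in these cells, at 135 ± 72.2 CPM (SD, n = 3; log2 fold change 6.40). So were GLIS1 and EPDR1, with log2 fold changes of 4.79 and 4.30.

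Of the 42 glaucoma and eye pressure genes tested, 18 rose and 0 fell in juxtacanalicular cell-like cells (20 and 0 adjusted over the list alone). In fibroblast-like cells 22 rose and 3 fell (23 and 4 adjusted over the list alone). These included CYP1B1, a cytochrome P450 mutated in primary congenital glaucoma, at 510 ± 103 CPM (SD, n = 3; log2 fold change 4.82), and FBN1, the gene for fibrillin 1, with 4.93. LMX1B had a log2 fold change of 4.83 there. In smooth or ciliary muscle-like cells 16 rose and 5 fell (16 and 5 adjusted over the list alone). DGKG, a diacylglycerol kinase gene, reached 633 ± 150 CPM with a log2 fold change of 6.65, and KALRN, the kalirin gene, 1120 ± 93.9 CPM with 5.99 (SD, n = 3 each). In vessel endothelium-like cells 12 rose and 2 fell (12 and 3 adjusted over the list alone), with CAV1 and CAV2, the caveolin genes at a locus linked to open-angle glaucoma, at log2 fold changes of 4.95 and 2.93. DGKG fell there by 2.63.

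Pigment cell-like cells had 7 genes of this list higher and 1 lower (9 and 2 adjusted over the list alone), among them CAV1 with 3.93, CAV2 with 2.49 and OPTN, the optineurin gene of normal-tension glaucoma, with 2.35. In Schwann cell-like cells 6 rose and 1 fell (8 and 1 adjusted over the list alone), with GAS7 at 492 ± 102 CPM (SD, n = 3; log2 fold change 4.22), FMNL2 at 1.69 and CAV1 at −4.30. In epithelium-like cells, tested in 2 libraries, 8 rose and 8 fell (8 and 8 adjusted over the list alone). PAX6, the master regulator of eye development, reached 677 ± 313 CPM (SD, n = 2; log2 fold change 6.70), MEIS1 had 5.54, and PDE7B had −3.93. In macrophage-like cells 2 rose and 7 fell (2 and 7 adjusted over the list alone), with CAV1 at −4.08 and FERMT2 at −3.05. In T or NK cell-like cells 1 rose and 5 fell (1 and 6 adjusted over the list alone); the gene that rose was ETS1, a lymphoid transcription factor, at 892 ± 268 CPM (SD, n = 2; log2 fold change 3.94).

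MYOC was called in other classes as well. Its log2 fold change was 2.86 in fibroblast-like cells (SE 0.50, adjusted p 0.000536) and 2.41 in muscle-like cells (SE 0.52, adjusted p 0.00180) by edgeR's quasi-likelihood test. These contrasts are against the mean of the other classes' log levels. Against their arithmetic mean, which the juxtacanalicular level dominates, MYOC was lower in both classes in 3 of 3 libraries, at 929 against 1564 CPM in fibroblast-like cells and 452 against 1624 CPM in muscle-like cells. MYOC fell by 3.16 in vessel endothelium-like cells (adjusted p 0.0438; lower in 3 of 3 libraries) and by 3.19 in epithelium-like cells (adjusted p 0.0269; lower in 2 of 2 libraries). It did not pass the test in macrophage-like (−1.46, adjusted p 0.167), pigment cell-like (−1.74, 0.181), Schwann cell-like (−0.90, 0.588) or T or NK cell-like cells (−1.69, 0.393), where it was lower than the arithmetic mean of the other classes in every library tested.

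A MYOC UMI was found in 35.5%, 33.2% and 85.1% of muscle-like cells of the trabecular, 5-year and 22-year corneoscleral libraries, with median depths of 1551, 1782 and 8057 UMIs. The background was read from macrophage-like cells, a class not known to make myocilin, where the shares were 3.64%, 6.57% and 6.67% at medians of 1494, 1807.5 and 3118 UMIs. With each cell thinned to 1000 UMIs, the muscle-like shares were 25.8%, 22.3% and 50.7% and the macrophage-like shares 3.16%, 3.29% and 2.22%. Thinning left out 80, 64 and 7 cells of the 3 libraries.

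**Figure D2:**
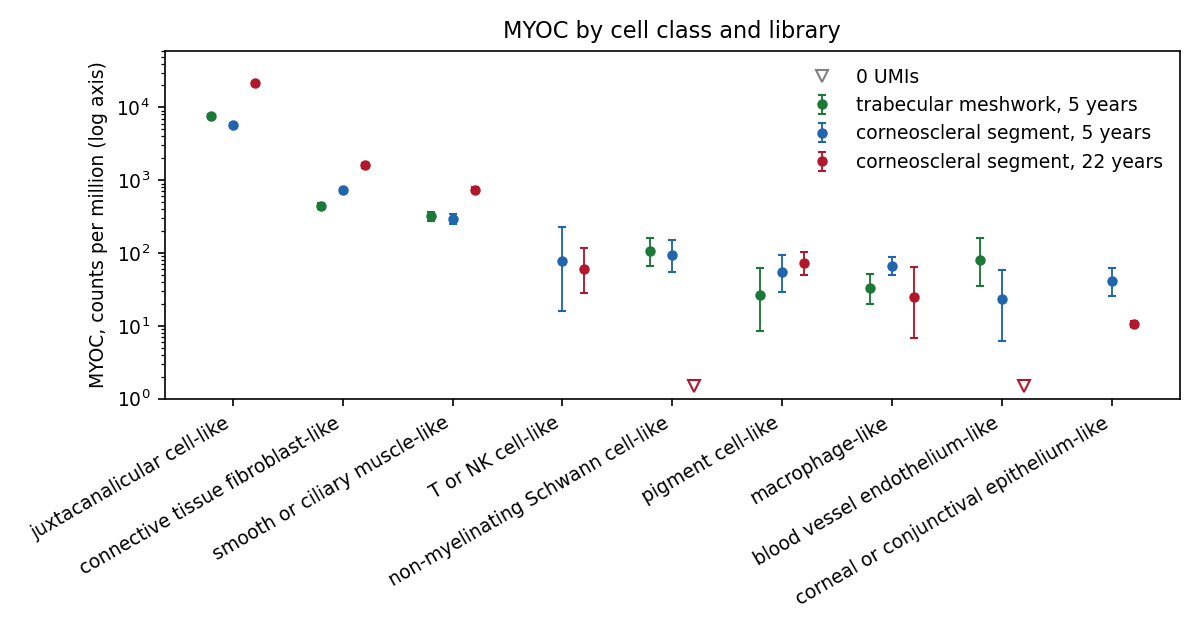
MYOC level in each named class (CPM, log axis), 1 point per library with an exact Poisson 95% interval; open triangles mark 0 UMIs. Juxtacanalicular cell-like cells hold 5823 to 21850 CPM and lie above every other class shown in each of the 3 libraries.

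Receptors aimed at by pressure-lowering drugs differed between the classes. CHRM3, the muscarinic receptor through which pilocarpine contracts smooth muscle, reached 1258 ± 237 CPM in muscle-like cells (SD, n = 3), with a log2 fold change of 7.15 (SE 0.27; adjusted p 1.78e-17 by edgeR's quasi-likelihood test; higher in 3 of 3 libraries). KCNJ8, a subunit of an ATP-sensitive potassium channel, had 5.42 there, and NR3C1, the glucocorticoid receptor gene, fell by 2.06. The list and its counts include NR3C1, although it is not a target of pressure-lowering drugs. ADRA2C and ADRA2A, genes of the alpha-2 adrenergic receptors that brimonidine activates, had 6.94 and 5.52 in juxtacanalicular cell-like cells, with ADRA2C at 98.7 ± 26.7 CPM (SD, n = 3; adjusted p 4.61e-10; higher in 3 of 3 libraries). CA12, a carbonic anhydrase gene, had 5.41 there.

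Of the 18 drug target genes tested, 7 rose and 0 fell in juxtacanalicular cell-like cells (7 and 0 adjusted over the list alone) and 4 rose and 1 fell in muscle-like cells (4 and 1 adjusted over the list alone). In fibroblast-like cells 8 rose and 1 fell (9 and 1 adjusted over the list alone), among them PTGER2, the gene of the prostaglandin EP2 receptor, at 127 ± 46.9 CPM (SD, n = 3; log2 fold change 4.61), ADRA2A with 5.23 and EDNRA, an endothelin receptor gene, with 4.13. In vessel endothelium-like cells 7 rose and 1 fell (7 and 1 adjusted over the list alone), with GUCY1A1 and GUCY1B1, the subunits of the nitric oxide receptor guanylate cyclase, at 3.52 and 2.5. Cluster 20, which held most of this class at 5 years, scored 2.89 for vessel endothelium and 2.18 for pericyte markers. No pericyte class was named, so these values are not tied to endothelial cells alone. Pigment cell-like cells had 3 higher and 0 lower (3 and 3 adjusted over the list alone), with EDNRB, the endothelin receptor of melanocytes, at 1822 ± 850 CPM (SD, n = 3; log2 fold change 6.54) and CA2 at 4.99. Macrophage-like cells had 6 higher and 1 lower (7 and 1 adjusted over the list alone), with ADORA3, an adenosine receptor gene, at 84.9 ± 26.3 CPM (SD, n = 3; log2 fold change 9.0) and PTGER4 at 3.64. Epithelium-like cells had 1 higher and 6 lower (2 and 8 adjusted over the list alone), with ADRB1, the beta-1 adrenergic receptor gene, at 3.70 and PTGER2 at −5.11. T or NK cell-like cells had 2 higher and 0 lower (2 and 0 adjusted over the list alone), with PTGER4 at 3.59, and Schwann cell-like cells 1 and 0 (0 and 0 adjusted over the list alone).

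Matrix genes were raised above all in fibroblast-like and juxtacanalicular cell-like cells. Of 30 outflow matrix genes tested, 28 rose and 0 fell in fibroblast-like cells (28 and 1 adjusted over the list alone). DCN, the gene for the proteoglycan decorin, reached 8228 ± 928 CPM there (SD, n = 3; log2 fold change 5.01), and COL1A1, VCAN and COL1A2 had 6.01, 5.95 and 5.12. In juxtacanalicular cell-like cells 22 rose and 0 fell (24 and 0 adjusted over the list alone). MGP, which encodes an inhibitor of calcification, reached 9828 ± 358 CPM (SD, n = 3; log2 fold change 5.02), BGN had 4.79 (SE 0.24; adjusted p 1.08e-15 by edgeR's quasi-likelihood test; higher in 3 of 3 libraries), and FBN2 and THBS1 had 5.63 and 3.75. Schwann cell-like cells had 13 higher and 0 lower (13 and 0 adjusted over the list alone), with COL3A1 at 4.6 and COL4A1 at 3.89. Vessel endothelium-like cells had 8 and 0 (8 and 1 adjusted over the list alone), with POSTN at 7.62, the basement membrane collagen gene COL4A1 at 5.47 and FN1 at 2.74. Muscle-like cells had 8 and 2 (8 and 3 adjusted over the list alone), with THBS2 at 3.59, COL5A2 at −2.36 and TIMP1 at −1.73. Fewer members rose than fell in epithelium-like cells, with 3 and 13 (5 and 14 adjusted over the list alone) and FN1 at −5.30 and TIMP2 at −4.95. The counts were 3 and 7 in macrophage-like cells (3 and 7 adjusted over the list alone), 3 and 5 in pigment cell-like cells (3 and 7 adjusted over the list alone), where TIMP2 had 2.83, and 0 and 5 in T or NK cell-like cells (0 and 6 adjusted over the list alone), where SPARC had −3.79.

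Of 28 genes of TGF-beta, BMP, WNT and stretch signalling, 14 rose and 1 fell in juxtacanalicular cell-like cells (15 and 2 adjusted over the list alone), with TGFB3 at 4.52 and BMPR1B at 4.06; the receptor gene TGFBR2 fell by 2.0. In fibroblast-like cells 13 rose and 0 fell (15 and 0 adjusted over the list alone). SFRP2 and DKK2, genes of secreted WNT modulators, had 6.27 and 5.73, and PIEZO2, a mechanically gated channel gene, had 4.85. In vessel endothelium-like cells 12 rose and 1 fell (13 and 1 adjusted over the list alone), with LEF1 at 4.75 and PIEZO1 at 2.18. TGFB1, the gene for transforming growth factor beta 1, had 4.83 in T or NK cell-like cells, where 4 rose and 6 fell (4 and 6 adjusted over the list alone), and 3.35 in macrophage-like cells, where 7 rose and 6 fell (7 and 7 adjusted over the list alone). It fell by 3.73 in muscle-like cells, where 4 rose and 5 fell (4 and 4 adjusted over the list alone), and by 2.24 in pigment cell-like cells, where 0 rose and 6 fell (1 and 7 adjusted over the list alone). Epithelium-like cells had 7 higher and 4 lower (7 and 4 adjusted over the list alone), with BMP7 at 4.59 and ID2 at −3.24. Schwann cell-like cells had 2 and 0 (2 and 0 adjusted over the list alone), with TGFBR2 at 1.80.

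The list of vessel growth and tone signalling was led by the vessel endothelium-like cells, where 15 of 21 genes rose and 1 fell (15 and 1 adjusted over the list alone). PTPRB, the phosphatase that restrains the TIE2 receptor, reached 477 ± 164 CPM (SD, n = 3; log2 fold change 8.68, SE 0.35; adjusted p 3.46e-18 by edgeR's quasi-likelihood test; higher in 3 of 3 libraries). TEK, which encodes TIE2, a receptor needed to form Schlemm's canal, reached 205 ± 109 CPM (SD, n = 3; log2 fold change 8.0), and TIE1 and NOS3 had 8.75 and 7.81. ANGPT1, the gene of a TIE2 ligand, rose in fibroblast-like cells, by 4.81, and in juxtacanalicular cell-like cells, by 3.90. SVEP1, a matrix protein gene linked to congenital glaucoma, had 6.33 in juxtacanalicular cell-like cells. The counts were 9 higher and 0 lower in fibroblast-like cells (10 and 0 adjusted over the list alone), with EDN3 at 6.01, and 6 and 0 in juxtacanalicular cell-like cells (7 and 0 adjusted over the list alone), with FLT1 at 4.95. Macrophage-like cells had 5 and 0 (4 and 0 adjusted over the list alone), with NRP1 at 3.82, muscle-like cells 4 and 0 (4 and 0 adjusted over the list alone), and Schwann cell-like cells 2 and 0 (2 and 0 adjusted over the list alone), with PDGFB at 4.69 and VEGFA at 3.84. Epithelium-like cells had 2 and 1 (2 and 1 adjusted over the list alone), with PDGFRB at −4.30, pigment cell-like cells 1 and 1 (1 and 0 adjusted over the list alone), with VEGFB at 2.37, and T or NK cell-like cells 1 and 2 (1 and 2 adjusted over the list alone).

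Over all classes and lists the test made 327 calls of a higher and 108 of a lower level. Among all genes tested, called higher levels made up 7.18% in T or NK cell-like, 9.62% in Schwann cell-like, 10.98% in pigment cell-like, 11.5% in juxtacanalicular cell-like and 12.99% in vessel endothelium-like cells. They made up 16.6% in fibroblast-like and in epithelium-like, 22.4% in macrophage-like and 24.1% in muscle-like cells, and lower levels 2.32% (pigment cell-like) to 12.3% (muscle-like). Several list counts of higher levels lay near or below these shares. Among them in muscle-like cells were 4 of 18 drug targets, 8 of 30 matrix, 4 of 28 signalling and 4 of 21 vessel genes. Others were 5 of 21 vessel and 7 of 28 signalling genes in macrophage-like and 8 of 42 glaucoma genes in epithelium-like cells. Schwann cell-like cells had 2 of 21 vessel and 2 of 28 signalling genes. Such counts do not set a list apart from all genes tested. The number of lower calls was 39 without the 5-year corneoscleral library and 179 with the DESeq2 Wald test. Each contrast is against a mean of 8 classes, so it says where a gene stood above that mean, not that other classes lack it.

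**Figure D3:**
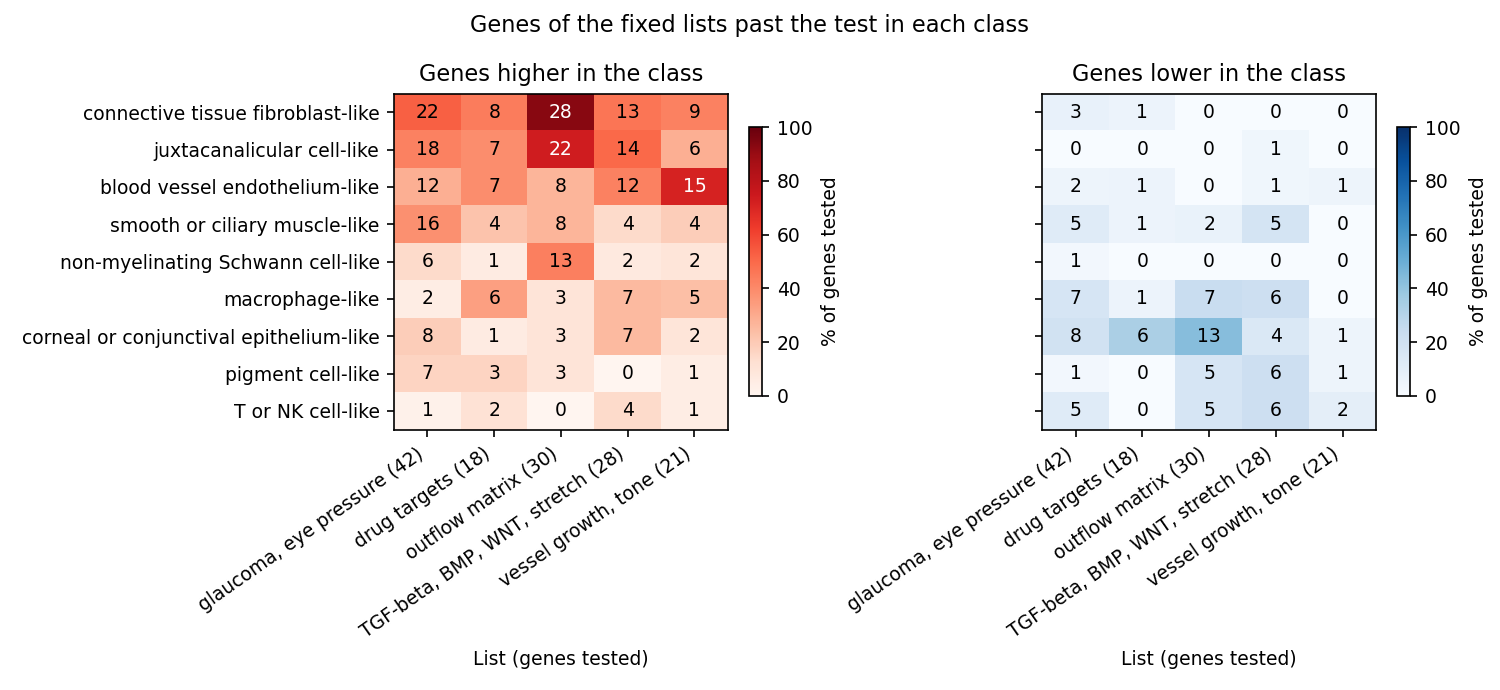
Number of genes of each tested list called higher (left) or lower (right) in each class by edgeR's quasi-likelihood test, with the share of the list's tested genes as colour (%). Fibroblast-like cells hold 28 of 30 matrix genes higher, and vessel endothelium-like cells 15 of 21 vessel genes.

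The trabecular meshwork and corneoscleral libraries at 5 years share age and chemistry and differ in dissection, the meshwork against the whole segment. The labels do not say whether they share the animal or the eye, so these cannot be told apart from the dissected tissue. In the fibroblast-like cells, compared over 707 against 941 cells, immediate early genes were lower in the trabecular library, and so were interferon, heat shock and oxidative stress genes. The median log2 ratio of the 17 immediate early genes, which cells switch on within minutes of a stimulus, was −0.74 (95% counting range −0.82 to −0.66), below each of the 10000 random lists, and the intervals of 16 lay below 0. MYC had −2.32, SOCS3 −1.35, KLF4 −1.34 and DUSP1 −0.90, against −1.52, −0.97, −0.71 and −0.89 in clusters 4 and 9 alone, where the median was −0.71. The same list had a median of −0.76 in muscle-like cells, with the intervals of 17 of 17 genes below 0, −0.65 in Schwann cell-like and −0.65 in pigment cell-like cells. Its median was 0.24 in macrophage-like cells and −0.13 in juxtacanalicular cell-like cells. In vessel endothelium-like cells it was 0.14 by CPM and −0.11 with TMM scaling.

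Heat shock genes had a median of −0.47 in the fibroblast-like cells (percentile 0.555 of random lists), with DNAJA1 at −0.77, DNAJB1 at −0.75 and HSPA8 at −0.60, against 0.47 in macrophage-like cells. The 12 detected interferon and antigen presentation genes had a median of −0.92 (percentile 0), with ISG15 at −2.56, IFI27 at −2.36 and IFI6 at −1.51. The 13 oxidative stress genes had −0.46 (percentile 0.100), with GPX3 at −3.79, FTH1 at −1.39 and SOD2 at −1.10. In the clusters 4 and 9 alone, which hold most fibroblast-like cells of both libraries, the interferon median was −0.17 and the oxidative median −0.26. The 5 detected senescence genes had −0.28 (percentile 11.5).

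Vessel growth and tone genes had a median of 0.65 in the fibroblast-like cells (0.26 to 0.74, above nearly all random lists), with EDN3 at 1.06 (0.89 to 1.22), FLT1 at 0.82 and KDR at 0.79, and SVEP1 at −1.55. In clusters 4 and 9 alone this median was 0.18, with EDN3 at 0.58, FLT1 at 0.21, KDR at 0.18 and SVEP1 at −0.22, the last 3 with intervals that hold 0. The outflow matrix list had −0.24 (−0.30 to −0.17; percentile 0.850), with COL6A3 at −1.78, COL1A1 at −1.68, VCAN at −1.58 and LOX at −1.55, and 0.03 in clusters 4 and 9 alone, where COL6A3 had −0.30 and COL1A1 −0.28. In the other direction, matrix genes had a median of 0.39 in juxtacanalicular cell-like cells (0.26 to 0.53), compared over 63 against 177 cells, and 0.19 with TMM scaling. By CPM the matrix median was 0.44 in Schwann cell-like, 0.34 in macrophage-like, 0.24 in pigment cell-like, −0.02 in vessel endothelium-like and −0.22 in muscle-like cells. The glaucoma list had 0.12 (percentile 86.0), with TRIOBP at −1.28, FBN1 at −1.26 and ABCA1 at −0.87; in clusters 4 and 9 alone the list had 0.01, and FBN1 (−0.15) and ABCA1 (−0.49) had intervals that hold 0. Drug targets had 0.03 (percentile 45.3), with PTGFR at −1.62, CA12 at −1.42, PTGER2 at 0.96 (0.64 to 1.29) and EDNRB at 0.88, against 0.41 (0.07 to 0.75) and 0.21 (−0.13 to 0.55) in clusters 4 and 9. The signalling list had 0.04 (percentile 49.1), with SFRP2 at −3.14, ID1 at −0.86 and SMAD7 at 0.72. MYOC had −0.72 (−0.88 to −0.56) in fibroblast-like and 0.39 (0.28 to 0.50) in juxtacanalicular cell-like cells, the latter 0.20 (0.08 to 0.31) with TMM scaling.

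Among single genes, the highest ratios in fibroblast-like cells were those of C15H9orf47 at 2.28 (1.38 to 3.27), SLCO1B1 at 2.16, ARHGAP19 at 1.64, SOX8 at 1.52 and the complement gene C7 at 1.51. ENPP2 at 1.49, COL13A1 at 1.48, ETV1 at 1.47, LCAT at 1.46 and CRHBP at 1.44 followed. CRHBP had −0.39 when each library was clustered alone. The lowest was CLEC3B at −9.0 (1 UMI against 830, interval −14.31 to −6.52). PLA2G2A had 0 against 789 UMIs, 162-fold lower with the floor of 3 UMIs, and its log2 interval ended at −7.04. Then came ALDH3A1 at −7.26 and the water channel gene AQP1 at −6.84 (1 UMI against 186, −12.15 to −4.35). FBLN2 had −5.56, IRX2 −5.55 (1 UMI, −10.87 to −3.03), C1QTNF3 −5.23 (1 UMI, −10.56 to −2.70) and LEPR −5.09. OSR2 had 0 against 180 UMIs, 37.0-fold lower with the floor of 3 UMIs, and its log2 interval ended at −4.90. CLEC3B, PLA2G2A and LEPR lead fibroblast cluster 13, which held 206 cells of the corneoscleral and 0 of the trabecular library, and ALDH3A1 is a keratocyte marker used for naming. In clusters 4 and 9 alone ALDH3A1 had −4.35, COL13A1 0.73, ETV1 0.82 and CRHBP 0.73. Different clusters thus held part of the class in the 2 libraries, with 462 and 307 cells in cluster 4, 210 and 241 in cluster 9 and 35 and 187 in cluster 14.

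The corneoscleral libraries at 22 and 5 years differ in age, in chemistry and, since eyes were removed after death, in the animal. The names of their cells hold TMRim at 22 years and CW at 5 years, which the labels do not explain. A difference in dissection is thus not ruled out, and no value below separates these. In the epithelium-like cells, with 3896 against 168 cells, heat shock, immediate early and senescence genes had medians above those of most random lists at 22 years. The highest log2 ratios were those of GSTA5 at 7.44 (1 UMI at 5 years, interval 4.96 to 12.74), S100A9, a calcium-binding alarm protein gene, at 6.80 (2 UMIs, 4.95 to 9.85), SERPINB2 at 5.93, MDM2, the gene of the ligase that degrades p53, at 5.43 (2 UMIs, 3.57 to 8.47) and HMOX1, the haem oxygenase of oxidative stress, at 5.07 (1 UMI, 2.59 to 10.38). The collagenase gene MMP1 had 9335 against 0 UMIs, 46.2-fold higher with the floor of 3 UMIs, and its log2 interval began at 5.23. IFFO2 had 4.93 (1 UMI, 2.45 to 10.23), MGST1 4.76 (1 UMI, 2.28 to 10.06), HBEGF 4.74 (3.87 to 5.81) and SCGB3A1 4.55 (1 UMI, 2.07 to 9.86). GSTA5 and S100A9 lead cluster 8 and HBEGF cluster 10, which held 506 and 416 cells at 22 years and 1 and 4 at 5 years, and SCGB3A1 leads an unnamed cluster.

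The lowest ratios were those of ANKS1B at −8.51, SCHIP1 at −6.19, SFRP4 at −5.66, 1 of the paired features of CNN3 at −5.24 and APOBEC3G at −5.19. LUM had −5.17, COL1A2 −4.78, PI16 −4.62, APOD −4.44 and TIMM8B −3.89. SCHIP1 leads cluster 27, which held 44 cells at 5 years and 2 at 22 years, but had −5.75 (−6.17 to −5.34) in clusters 1 and 6 alone too. SFRP4, LUM, PI16 and APOD are markers of fibroblasts or keratocytes that were used for naming. In clusters 1 and 6 alone, which both libraries hold, MDM2 had 5.40, SERPINB2 4.45, HMOX1 4.23 and ANKS1B −9.45. MDM2 and HMOX1 each rested on 1 UMI at 5 years there (2.92 to 10.71 and 1.75 to 9.54), and GSTA5, S100A9 and MGST1 had 0, so that no direction is given for these 3 genes within clusters 1 and 6.

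The median over all 13332 genes of this comparison was −0.32 by CPM and 0.15 with TMM scaling, a shift of 0.46, so list values are read against it. Heat shock genes had a median of 0.71 (0.59 to 0.91; percentile 99.1 of random lists), with DNAJA1 at 1.98 and HSPA8 at 1.22, and immediate early genes 0.50 (percentile 98.6), with SOCS3 at 1.98 and JUND at 1.40. Senescence genes had 0.29 (percentile 99.0), with CXCL8 at 4.0 (1 UMI at 5 years, 1.52 to 9.30), IGFBP3, which leads clusters 3 and 7, at 3.27 and PLAUR at 3.01. CDKN2B, the cell cycle inhibitor gene at a glaucoma locus, had 1.41 (0.86 to 2.01). Drug targets had 0.64 (percentile 99.6), with EDNRB at −3.63, PTGER4 at 3.53 (2 UMIs, 1.68 to 6.58), and CA12 at 2.07 (3 UMIs, 0.52 to 4.36), and oxidative stress genes 0.34 (percentile 94.4), with SOD1 at −1.71. The 6 detected vessel genes had 1.31 (0.44 to 1.56), with EDN1 at 1382 against 0 UMIs, VEGFA at 1.56 and ADM at 1.37. In clusters 1 and 6 alone the vessel median was 0.20, the immediate early median −0.01, the senescence median 1.18 and the interferon median 0.37. There PTGER4 had 0.50, VEGFA −0.05, ADM 0.20, SOCS3 0.84 and IRF1 0.63, each with an interval that holds 0. Outflow matrix genes had −0.77 (−1.18 to 0.01), with MGP at −3.64 and LOX at −3.16, and 0.14 in clusters 1 and 6. Fibroblast markers fell alike in these cells, and fibroblast-like cells fell from 37.2% to 2.86% of the library, so these falls are not told apart here from RNA of other cell types. Glaucoma genes had −0.31 by CPM and 0.15 with TMM scaling, with FERMT2 at 2.48 (2 UMIs, 0.62 to 5.52) and MYOC at −1.96, from 41.4 to 10.6 CPM, near the 67.1 and 24.7 CPM of macrophage-like cells. Signalling genes had −0.29, with BMP2 at 1783 and DKK3 at 1687 UMIs against 0 each and ID3 at 2.52. Interferon and antigen presentation genes had −0.19 (percentile 78.7), with IFIT2 at −2.0 and IRF1 at 1.55.

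Most senescence-list genes measured also had higher CPM at 22 years in the 4 classes compared outside the epithelium. Their median log2 ratio was 1.37 in fibroblast-like cells (1.21 to 1.62; 6 genes; 136 against 941 cells), 1.37 in vessel endothelium-like (6 genes; 65 against 87 cells), 1.36 in muscle-like (4 genes; 134 against 301 cells) and 2.46 in pigment cell-like cells (4 genes; 88 against 119 cells). With RNA of the epithelium subtracted in 3 versions, the muscle-like median was 1.18, −0.96 and −0.01 and the pigment cell-like median −1.04, −1.04 and 0.44, so neither class is read as raised. In muscle-like cluster 5 alone it was −0.30 (2 genes), in pigment cell-like cluster 22 alone −1.19 (1 gene), and in vessel endothelium-like cluster 23 alone 0.17 (−0.28 to 1.08; 3 genes). In fibroblast-like cells IL6, an inflammatory cytokine gene, had 3.32, CDKN1A, the cell cycle inhibitor p21, 1.67 and CCL2 1.42, and in vessel endothelium-like cells IL6 had 2.92 and CCL2 2.22. Intervals lay above and below 0 for 5 and 0 genes in fibroblast-like, 5 and 0 in vessel endothelium-like, 3 and 1 in muscle-like and 3 and 1 in pigment cell-like cells. The gene that fell was IGFBP5, at −0.55 in muscle-like and −1.85 in pigment cell-like cells, where IGFBP3 had 181 against 0 UMIs. The fibroblast-like cells also had a median of 1.09 for immediate early genes (1.03 to 1.20) and 1.31 for heat shock genes. Their matrix list had −0.42, against −0.83 in muscle-like and −1.32 in pigment cell-like cells. MYOC had 1.11 (0.98 to 1.24) in fibroblast-like and 1.36 (1.11 to 1.61) in muscle-like cells. Different clusters held most of these classes at the 2 ages: cluster 24, which IGFBP5 leads, most fibroblast-like cells at 22 years and clusters 4, 9, 13 and 14 at 5 years, cluster 21 against 5 for muscle-like, 22 against 15 for pigment cell-like and 23 against 20 for vessel endothelium-like cells. RNA of the epithelium was found in them, since the corneal keratin gene KRT12 had 264 to 1540 CPM in the non-epithelial classes at 22 years.

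**Figure D4:**
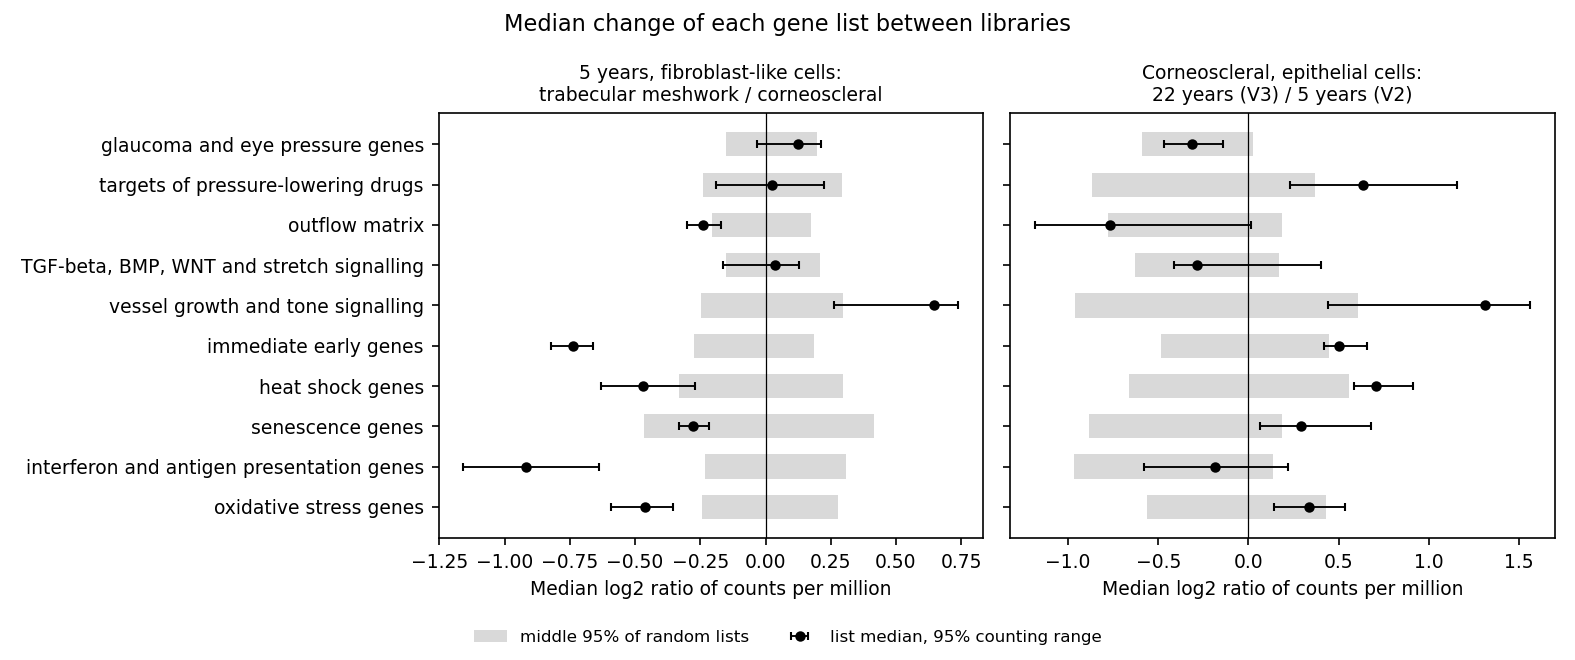
Median log2 ratio of CPM of each gene list (points, with 95% counting ranges as bars) in the fibroblast-like cells of the 5-year libraries, trabecular over corneoscleral (left), and in the epithelium-like cells of the corneoscleral libraries, 22 over 5 years (right). Grey bands hold the middle 95% of random lists matched on expression; immediate early genes lie at −0.74 on the left and 0.50 on the right.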

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

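No test stands in this part. The values below are signals in cells that no comparison above used, and in transcripts that none of them named. Unnamed cluster 17 held 145 cells, 0 in the trabecular, 7 in the 5-year and 138 in the 22-year corneoscleral library. SCGB3A1, PIGR and LTF, genes of secretory epithelium and its fluid, led it, and its best marker list was that of the ocular surface epithelium, but a marker of another class stood among its leading genes. Unnamed cluster 19 held 136 cells, 6, 48 and 82 in the same order, and was led by contractile and vessel wall genes such as TAGLN, MCAM and RGS5. Its cells scored almost alike for pericytes and for muscle, so neither name was given. Unnamed cluster 30 held 22 cells, 3, 13 and 6, with the antibody-secretion genes JCHAIN and MZB1 among its leading genes but only 2 supporting markers.

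Unnamed transcripts, which carry no gene symbol, held 25.4% of all UMIs in the trabecular library, 21.1% in the 5-year and 20.6% in the 22-year corneoscleral library. They counted toward the total of each library and were not left out of the clustering, the genes tested or the random lists. They were never named as results.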

How the results depend on the processing

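The alternatives restricted to some fibroblast-like or epithelial clusters, and the one that kept fibroblast-like clusters apart, were chosen only after the result was seen. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The contrasts of endothelia, of trabecular cells and of contractile cells gave no value under any alternative.

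The 327 higher calls ran from 243 to 437 over the alternatives. The 108 lower calls became 179 with the DESeq2 Wald test, 167 with at least 50 cells, and 39 to 119 with 1 library left out, 39 being without the 5-year corneoscleral one. Leaving out a library assumes that the other 2 stand for it and leaves fewer samples per class. MYOC in juxtacanalicular cell-like cells kept its call in 17 alternatives, at 6.03 to 7.37; with 1000 variable genes the class was too small to test. Of single genes between classes, 2511 values stayed on their side of the threshold, 171 lost their call and 3 gained one.

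The juxtacanalicular share of the 5-year corneoscleral library was 9.34% and 8.19% at resolution 0.5 and 2, 0.0791% and 9.18% with 1000 and 4000 variable genes, 8.43% clustered alone and 8.92% without doublets. In the trabecular library it was 0 with 1000 variable genes and 0 clustered alone. The epithelial share at 22 years was 80.4% with 1000 variable genes and 68.3% clustered alone.

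In fibroblast-like cells between the 5-year libraries, the matrix median was −0.30 with TMM and 0.0295 in clusters 4 and 9, drug targets 0.30 at a minimum of 200 UMIs and 0.23 clustered alone, the vessel list 0.16 clustered alone and 0.18 in clusters 4 and 9, and CRHBP turned from 1.44 to −0.39 clustered alone. Immediate early genes in vessel endothelium-like cells turned from 0.14 to −0.11 with TMM.

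In epithelium-like cells between ages, TMM turned the glaucoma list from −0.31 to 0.15 and gave 1.78 for the vessel list. The matrix median was 0.15 at a minimum of 200 UMIs, −1.50 clustered alone and 0.14 in clusters 1 and 6, where the vessel list had 0.20 and immediate early genes −0.0114. SCGB3A1 turned from 4.55 to −4.87 clustered alone. In clusters 1 and 6, MYC had −0.0114, VEGFA −0.0539 and ZFP36 −0.17; S100A9 (−0.62) and MGST1 (−1.08) had 0 UMIs at 5 years there and stand against the floor of 3. In pigment cell-like cells, interferon genes turned from 0.48 to −0.33 and CD74 from 0.73 to −0.87 as means over cells. Of the medians of the 5 tested lists in the leading classes 73 stayed, 10 moved and 2 turned; of all other list medians 595, 52 and 3 did. A change of sign counts as turned only where the unaltered value's own range leaves out 0, which that of the epithelial matrix and interferon medians does not. For these changes the cause was not tested, except that restricting clusters leaves out cells and TMM shifts all genes.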

Other observations

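In this part, the contrasts that kept fibroblast-like clusters apart were chosen only after the result was seen. So were the tests of free RNA, of 20 genes 1 by 1 in muscle-like cells and of UMIs per cell. The tests of handling that acts on every cell alike, of library chemistry and of clusters 5, 22 and 23 were also chosen then.

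The clusters of fibroblast-like cells were also set against the other classes 1 by 1. With these clusters kept apart as classes, edgeR's quasi-likelihood test gave SFRP2, a gene of a secreted WNT modulator, a log2 fold change of 7.07 in cluster 13 (SE 0.39), which came from the corneoscleral libraries alone, with SVEP1 at 6.72 and COL1A1 at 6.65. In cluster 14 VCAN had 8.07 and the adrenergic receptor gene ADRA2C 5.89. Cluster 4 had EDN3 at 5.11, KDR at 4.11 and BMP4 at 4.06, and cluster 9 had FBN2 at 4.27, LMX1B at 4.11 and CYP1B1 at 4.02. Juxtacanalicular cell-like cells had ADRA2C at 6.80 and MYOC at 6.68 in the same fit. Whether the clusters differed from each other was not tested.

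Muscle-like cells held MYOC RNA in all 3 libraries, at 9.77 (6.15 to 16.4), 4.34 (3.18 to 5.99) and 30.1 times (11.7 to 111) the level of macrophage-like cells in the trabecular, 5-year and 22-year corneoscleral libraries, and free RNA and doublets were weighed as technical explanations. Free RNA would give MYOC a fold like that of RNA from other cell types, but the highest such fold among the marker lists of pigment cells, Schwann cells, vessel endothelium and epithelium with enough UMIs was 0.580, 0.759 and 0.381, so that MYOC's fold was at least 5.71 times as high, with intervals apart in each library, though 0.381 rests on the epithelial list alone, and the Schwann and pigment cell lists, with 24 and 17 UMIs in muscle-like against 0 in macrophage-like cells, were too few to bound the fold at 22 years. In earlier versions, free RNA was taken to differ by at most 2 times between classes. KRT12, at 462 CPM in muscle-like and 1540 CPM in macrophage-like cells at 22 years, contradicts that. Earlier versions also divided MYOC's muscle share of its juxtacanalicular level by the median share of 20 genes. This gave 0.693, 0.634 and 0.525 and met its own bound for free RNA, with 12 of the 20 above MYOC's share in every library. The 20 were chosen for high levels in juxtacanalicular cell-like over macrophage-like cells alone, so muscle cells making them was not ruled out. Not all are specific against muscle-like cells, where RGS5 stood at 68.9%, 67.1% and 62.5% of its juxtacanalicular level. Free RNA or doublets from juxtacanalicular cell-like cells alone would bring all 20 along at no less than MYOC's share. Against that, 6 of them lay below it in every library with intervals apart, MGP at 1.43%, 1.89% and 0.11% against 4.198%, 5.0% and 3.41% for MYOC. Muscle-like cells with a MYOC UMI held the 20 at a median of 6.25%, 6.93% and 6.55% of the juxtacanalicular level, against 5.22%, 8.03% and 5.58% in those without. These medians lay below the 10% set before for doublets with juxtacanalicular cells. Fibroblast-like cells also held MYOC RNA, and their markers were not among the lists compared. Doublets with them were not tested either, so MYOC RNA from fibroblast-like cells stays open. Expression of MYOC by muscle-like cells may be 1 of the remaining explanations, a hypothesis found and tested on the same cells, and no biological explanation was tested.

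Immediate early genes were lower in trabecular than in corneoscleral fibroblast-like cells at 5 years, with a median log2 ratio of −0.74. Fewer UMIs per cell as the whole cause would not leave the median at −0.60 (−0.69 to −0.48, bound −0.4) when 525 cells of each library were matched on their UMIs. The smaller value may come from depth or from which cells were kept, and these were not separated. An earlier version thinned the cells, which cannot move such a ratio (−0.73), and was dropped after it was seen. Other clusters in the class would not leave it at −0.71 (−0.81 to −0.64; bound −0.4, set before) in clusters 4 and 9 alone, with 672 against 548 cells. Handling that acts on every cell alike was at odds with the median of 0.24 in macrophage-like cells (0.12 to 0.30). Open are handling that acts on some cell types, a difference between animals and the dissected tissue itself, which 1 library per group cannot separate.

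Most senescence-list genes measured were higher at 22 years in fibroblast-like, vessel endothelium-like, muscle-like and pigment cell-like cells, with medians of 1.37, 1.37, 1.36 and 2.46. Other clusters in the class would not leave the median of fibroblast-like cells at 1.39 (1.12 to 1.72; 4 genes; 34 against 206 cells) in cluster 13 alone, but cannot be told apart in vessel endothelium-like cluster 23 (0.17, −0.28 to 1.08; 3 genes), muscle-like cluster 5 (−0.30; 2 genes) and pigment cell-like cluster 22 (−1.19; 1 gene), where too few genes passed the floor of 3 UMIs or the range is wide. Free RNA from the epithelium was subtracted in 3 versions, each tried after the one before it was seen, of which the prediction for the earliest had been written before and treated the 4 classes together: with the profile of all epithelial cells and 4 keratins the medians were 1.37, 1.36, 1.18 and −1.04 in the same order, with clusters 3 and 7 and 4 keratins 0.73, 1.26, −0.96 and −1.04, and with clusters 3 and 7, KRT5 and KRT15 they were 1.37, 1.35, −0.01 and 0.44. The epithelial share subtracted at 22 years ran from 4.29% to 100%, and free RNA stays open in fibroblast-like (lower end 0.44 in 1 version), muscle-like and pigment cell-like cells, while in vessel endothelium-like cells every version stayed above 0.7 (lowest 1.26, lower end 1.05), at odds with these profiles as the whole cause. Chemistry cannot be told apart from age, animal or dissection. The intervals of 3 of 6 genes overlapped in all classes that measured them (CCL2, CDKN1A and IL6) and those of IGFBP3, IGFBP5 and IGFBP7 did not.

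Of 25 assignments of class names within libraries (1 split of the cells each, the real one included), 1 gave as many as the real 435 calls, the real one itself, and the highest of the others gave 29. The classes were clustered from other genes of the same cells, which made more calls than under shuffled names near certain beforehand, so this count excludes nothing and does not test the list genes.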
